A study of Mus musculus with 6 samples.

How the data were processed

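RNA was sequenced from 6 samples of the mouse line mDE6, 3 with a control hairpin and 3 with a hairpin against Arl4c. Total RNA was isolated with TRIzol and a Promega spin kit and libraries were made with a directional MGI kit, per the labels' protocols. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not describe the tissue of origin of the line or the hairpin sequences.

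The authors deposited 1 table of normalised values per gene and library, in CPM. Trimmomatic 0.38, RSEM 1.3.0, Bowtie2 and edgeR were used, per the submitters' processing notes, which give neither their order nor their settings, and the genome build was GRCm39. Whether reads were counted by strand is not given in the sources used here, so genes that overlap on opposite strands may share reads. The column totals, 969971 to 1019097 CPM, were not equal. Every value was a whole multiple of the smallest value of its column (100% of values, within a tolerance of 0.001 of a read), so the deposited CPM values could be turned back into read counts. The totals of these counts were 13639195, 14976113 and 12316770 in shControl 1, 2 and 3 and 13780358, 12941166 and 13033169 in shArl4c 2, 3 and 4. The authors' scaling factor, the divisor they used over the library total, ran from 0.981 to 1.03 and matched edgeR's trimmed mean of M-values (TMM). The smallest total of any listed gene was 6 reads over the 6 libraries, so genes below that were not analysed here. A count of 0 allows up to 3 reads, or 0.202 to 0.248 CPM per library. Such floors cover counting error only.

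The columns of the table carry names other than the sample titles. Columns named shluc were taken as shControl, the only group without an Arl4c hairpin, and the columns naming the Arl4c hairpin, numbered 2 to 4 and with a misspelt gene name, as shArl4c. All columns were mapped to a group and to no single sample. Of 22032 gene identifiers, 21880 matched a gene symbol in a name table, 152 did not and kept their identifier, and 21 shared a symbol with a more abundant gene. The annotation at hand was of an older mouse build than GRCm39, so no coordinates are given, and it served only for symbols, gene types, and the GC content and length of transcripts.

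Genes with a mean of at least 1 CPM over the 6 libraries were kept (14740; 7292 fell below). Values were taken to log2(CPM + 1) and fitted with limma 3.58.1 in R 4.3.3, shArl4c against shControl with no covariate, with an intensity trend and robust empirical Bayes moderation. P-values were adjusted over all tested genes by the method of Benjamini and Hochberg, and a gene was called changed at an adjusted p under 0.05. Gene lists (24) were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists, and counts of members were also adjusted over the list alone. The design, the lists, the thresholds and the rule for naming genes were fixed before the data were examined, as were all alternatives other than plain CPM, the correction for GC content and length, and the counts of list members without shArl4c 3, which were chosen after seeing the data. The design allowed for several units and its CPM form was used.

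Named genes were Arl4c; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, groups that did not overlap and a mean of at least 5 CPM, leaving out predicted genes, pseudogenes and genes with no symbol; and the 3 members of each list with the smallest p, of those past the threshold. This gave 84 different genes. The results of 1 of the 24 lists and of 1 further gene are not reported here. Any other gene named is said to have been chosen after its values were seen.

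As alternatives, the pseudocount was set to 0.5 and 5, the filter dropped or raised to 5 CPM, values rescaled by TMM, by median of ratios or by quantiles, limma run without trend and robust moderation or with array weights, and each library left out in turn. Recovered reads were tested with the quasi-likelihood test of edgeR 4.0.16, which called 5378 genes, and with DESeq2 1.42.0, which called 4108. Pairs of libraries were compared by chi-square over genes with at least 20 reads. The steps were tested on simulated counts drawn from the real means and library sizes over 14740 genes, with 50 genes changed at each fold size. For shArl4c against shControl, limma recovered 50% of simulated 1.25-fold changes, 62% of 1.5-fold, 82% of 2-fold and 96% of 4-fold changes, and 5.20% of its 173 calls were false. Camera called the 1 shifted list and 0 of 23 unshifted lists. The simulated genes were drawn independently of each other, and far fewer were changed than in the data. The simulation therefore does not test camera on lists whose genes vary together, such as the ribosomal protein list (estimated correlation 0.74).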

Results

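Gene expression was measured by RNA sequencing in mDE6, a mouse cell line, carrying either a control short hairpin RNA (shControl) or a hairpin against Arl4c (shArl4c), a small GTP-binding protein of the ARF family. Each group had 3 libraries. They are named here by the numbers in the deposited table, shControl 1, 2 and 3 and shArl4c 2, 3 and 4. The libraries held 12316770 to 14976113 reads, recovered from the deposited CPM values (read counts scaled to a common library size), so that 1 read was worth 0.0672 to 0.0827 CPM. The table listed 22032 genes, of which 14740 had a mean of at least 1 CPM and were tested. Values are given as mean ± SD over n = 3 libraries per group unless another form is stated. Fold changes on the log2 scale are of CPM + 1, which understates the change of genes at low levels.

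The libraries separated by group. The first principal component of the log2 values held 73.9% of the variance and split shControl from shArl4c, and the second held 10.9%. Counts differed by a chi-square per degree of freedom of 1.54 to 5.74 within groups and of 28.1 to 32.7 between groups. All pairs, replicates included, differed by more than sampling noise. Each library was counted once, but this excess does not show that the libraries came from separate cultures. Library shArl4c 3 stood apart from its group: its chi-square per degree of freedom was 5.74 against shArl4c 2 and 4.87 against shArl4c 4, while shArl4c 2 and 4 differed by 1.54. The 10 most abundant genes took 8.16% to 8.46% of the reads in shControl and 6.76% to 7.02% in shArl4c.

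mDE6 cells expressed genes of mesenchymal cells in both groups. In shControl, Vim, an intermediate filament protein, stood at 2543 ± 51.6 CPM, the type I collagen gene Col1a1 at 17787 ± 480.4 CPM and Twist1 at 42.7 ± 1.41 CPM. Of epithelial keratin genes, Krt80 had a mean of 12.1 CPM, Krt7 of 2.04 CPM and Krt10 of 1.79 CPM in shControl, and the means in shArl4c were 24.5, 2.17 and 1.62 CPM. Krt14, Krt5, Krt8 and the E-cadherin gene Cdh1 were at lower levels: Krt14 stood at 0.708 ± 0.329 CPM, Krt5 at 0.166 ± 0.0945 CPM, Krt8 at 0.0970 ± 0.0328 CPM and Cdh1 at 0.321 ± 0.0223 CPM in shControl. The corresponding shArl4c values were 1.24 ± 0.438, 0.0997 ± 0.0435 and 0.198 ± 0.111 CPM for these last 3 keratins, and no read of Cdh1 was recovered from any shArl4c library, which allows up to 0.218 to 0.230 CPM per library. Trp63, an epithelial transcription factor, was detected at 5.17 ± 0.254 CPM in shControl and 6.37 ± 0.178 CPM in shArl4c. Apart from Krt80, the genes in this paragraph were chosen after their values were seen, as a description of the line.

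The series asks what changes when Arl4c is depleted, and its title places the question in tooth germ development and osteoblastic differentiation. Arl4c was lower in all 3 shArl4c libraries. It stood at 20.7, 21.0 and 20.1 CPM in shControl 1, 2 and 3, and at 6.75, 7.42 and 6.89 CPM in shArl4c 2, 3 and 4. The means were 20.6 ± 0.480 and 7.02 ± 0.354 CPM (SD, n = 3), a 2.94-fold lower level and a log2 fold change of -1.43 (SE 0.09, limma adjusted p = 2.08e-10). Of its relatives, Arl4d had a log2 fold change of -0.55 and Arl4a one of 0.51, and both passed limma's test. These 2 were chosen after their values were seen.

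Many genes differed between the groups. The labels tell apart 1 Arl4c hairpin group, so effects of less Arl4c and other effects of the hairpin cannot be told apart for any of them. Other differences between the cultures of the 2 groups cannot be told apart from these either, since the labels do not state separate cultures. The largest falls included the matrix genes Tnn, Fbn2 and Postn, and the largest rises Pcdh7 and the interferon-induced genes Oas3, Oas1a and Oas2. By limma, 5445 of 14740 genes (36.9%) changed, 2790 higher and 2655 lower in shArl4c. At least 2-fold changes were seen in 558 genes, 185 higher and 373 lower, against 235 genes with a pseudocount of 5 and 342 with the stricter filter. The 2 groups did not overlap in 6905 genes, or 46.8%, where chance would give 10%.

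Tnn, encoding the matrix glycoprotein tenascin N, fell the most of the named genes, from 596 ± 7.26 to 14.0 ± 0.430 CPM, 42.7-fold lower (log2 fold change -5.32, SE 0.04, limma adjusted p = 1.14e-23). Fbn2, encoding the microfibril protein fibrillin 2, fell 40.1-fold, from 155 ± 0.841 to 3.88 ± 1.11 CPM (limma adjusted p = 2.73e-06). Postn, encoding the matrix protein periostin, fell 16.2-fold from 517 ± 13.1 to 31.8 ± 1.61 CPM. Tnc, encoding tenascin C, fell 10.9-fold from 251 ± 9.15 to 23.01 ± 1.40 CPM. Collagen genes were also among the 10 largest falls: Col6a3 went from 411 ± 2.41 to 36.9 ± 2.97 CPM, 11.1-fold lower, and Col11a1 from 37.1 ± 1.59 to 1.55 ± 0.548 CPM, 23.98-fold lower. The other 4 were Spock2 (18.4-fold lower), Pgm5 (23.1-fold), Fndc1 (14.5-fold) and Actg2 (11.6-fold), the last encoding smooth muscle gamma-actin. The limma adjusted p of these 10 genes was 2.73e-06 for Fbn2 and smaller for the others.

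The largest rises included 4 interferon-induced genes. Oas3 went from 2.02 ± 0.433 to 26.5 ± 0.885 CPM, 13.1-fold higher (log2 fold change 3.20, SE 0.12, limma adjusted p = 8.93e-14). Oas1a rose 14.8-fold from 1.39 ± 0.267 to 20.6 ± 1.33 CPM and Oas2 13.4-fold from 1.82 ± 0.231 to 24.4 ± 3.56 CPM. Rsad2, encoding the antiviral protein viperin, rose 6.94-fold from 1.57 ± 0.211 to 10.9 ± 0.328 CPM. Pcdh7, a protocadherin gene, had the largest rise on the log2 scale, 3.37, from 4.88 ± 0.269 to 59.7 ± 4.39 CPM. Syt7, a synaptotagmin gene, rose 9.45-fold to 73.3 ± 1.31 CPM and Itgb7, an integrin subunit gene, 5.24-fold to 151 ± 9.998 CPM. Msln, encoding mesothelin, rose 4.997-fold to 102 ± 4.86 CPM, Nr5a2, a nuclear receptor gene, 8.78-fold to 10.6 ± 0.993 CPM, and Prl2c2 5.87-fold to 159 ± 8.57 CPM. Oas1a and Prl2c2 belong to clusters of closely similar genes, so the split of reads between them and their neighbours is uncertain.

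**Figure D1:**
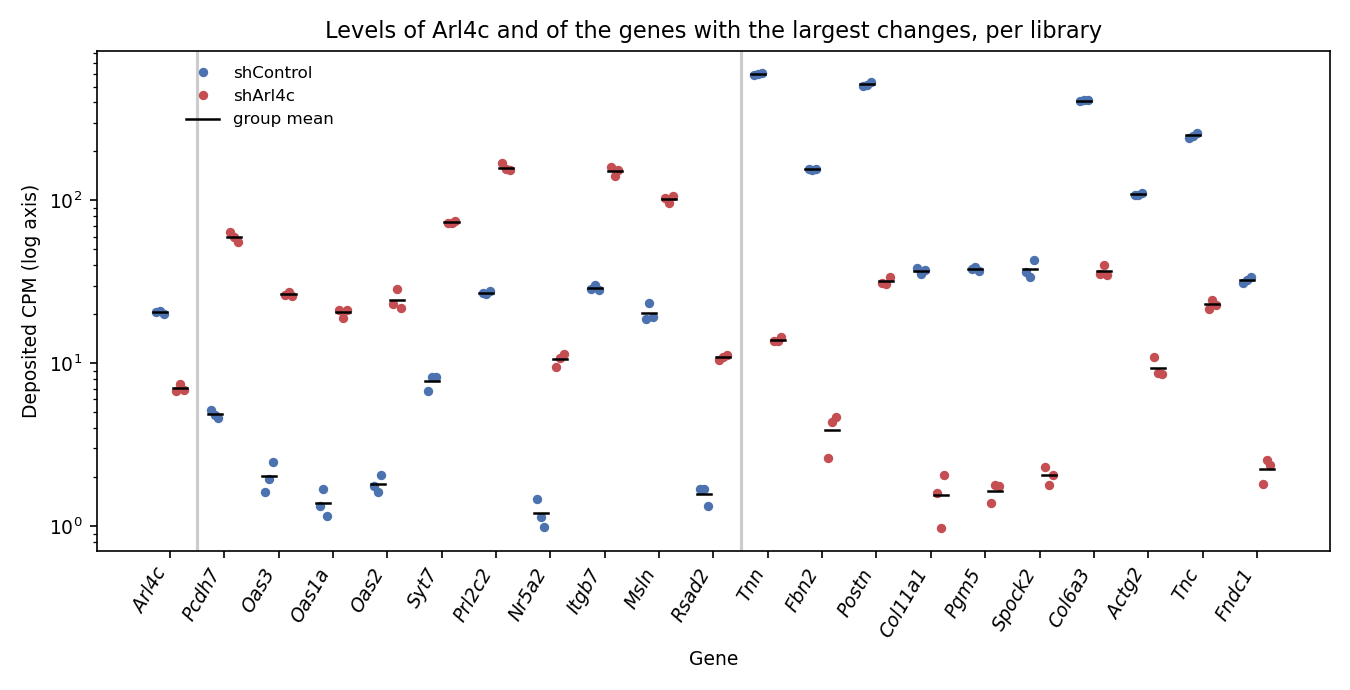
Deposited CPM (log axis) of Arl4c, of the 10 genes with the largest rises and of the 10 with the largest falls, 1 point per library (blue, shControl; red, shArl4c) with a black line at each group mean. No shArl4c point of any gene drawn lies within the range of the shControl points, which the naming rule required of the rises and falls. Tnn goes from 596 to 14.0 CPM.

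**Figure D2:**
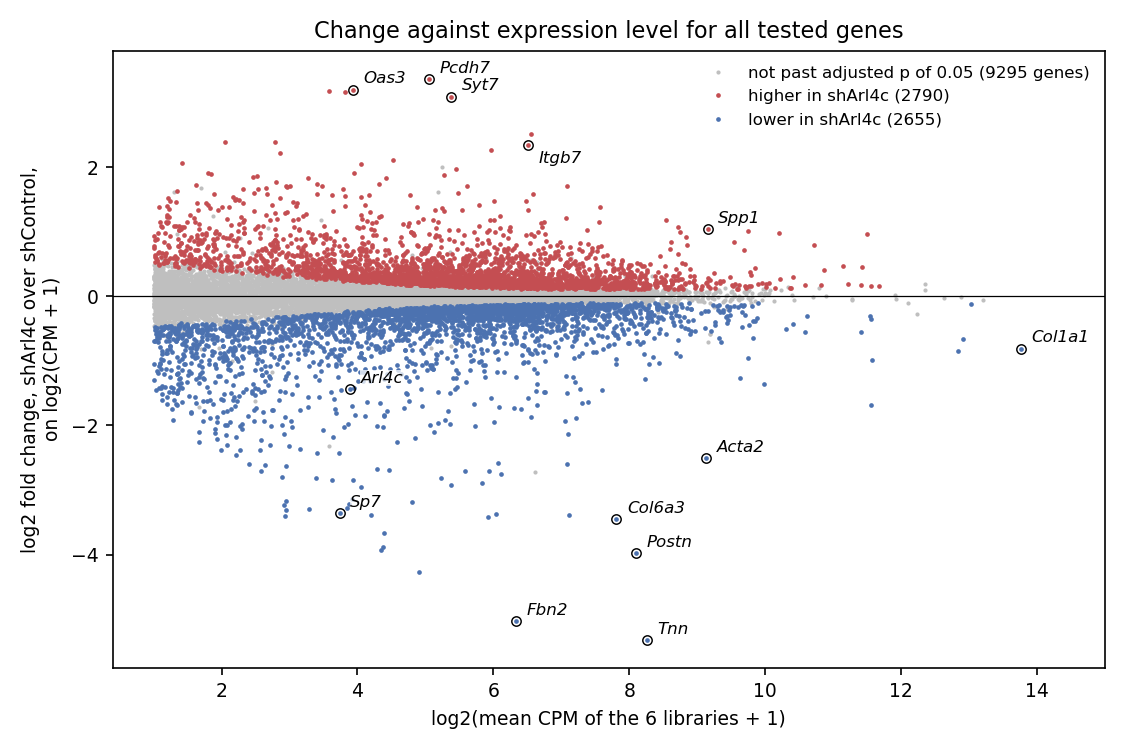
Log2 fold change of shArl4c over shControl (on CPM + 1) against the log2 mean CPM + 1 of the 6 libraries, 1 point per tested gene; red and blue mark the 2790 higher and 2655 lower genes, grey those not past the limma adjusted p of 0.05, and black rings the labelled genes. The labelled falls reach -5.32 for Tnn, and the labelled rises 3.37 for Pcdh7.

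Genes of contractile fibres and of the actin cytoskeleton fell together. Of 27 tested genes of the list of SRF targets and actin cytoskeleton, 25 fell, none rose and 2 did not pass the test. Acta2, encoding smooth muscle alpha-actin, fell 5.68-fold from 956 ± 17.7 to 168 ± 11.1 CPM (log2 fold change -2.50, SE 0.05, limma adjusted p = 3.84e-18). Cnn1, encoding calponin, fell 7.73-fold from 65.0 ± 1.63 to 8.41 ± 0.530 CPM, and Actg2 from 109 ± 1.68 to 9.41 ± 1.28 CPM. The median log2 fold change of the list was -0.39 and its mean -0.90, and the same 25 lower and 0 higher were counted when adjusted over the list alone. The abundant actin genes Actb (log2 fold change -0.12) and Actg1 (-0.30) fell by less than the genes above, and Myh9 (-0.04) and Zyx (-0.04) did not pass. Actb, Actg1, Myh9 and Zyx were chosen after their values were seen. Limma's camera called the list lower with a preset correlation of 0.01 (adjusted p = 6.86e-15) but not with an estimated correlation (adjusted p = 0.203 with an estimated correlation).

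Genes of fibroblasts and of epithelial-mesenchymal transition were mostly lower. Of 34 tested members, 23 fell, 7 rose and 4 did not pass, with a median log2 fold change of -0.59. Col6a3 and Acta2, given above, led the falls by p, followed by the collagen gene Col5a1, which fell 2.57-fold from 1465 ± 31.9 to 569 ± 2.67 CPM. The abundant type I collagen and fibronectin genes were lower too: Col1a1 went from 17787 ± 480.4 to 10139 ± 207 CPM and Fn1 from 9430.2 ± 168 to 5934 ± 199.8 CPM. Members that rose included S100a4 (log2 fold change 1.15), Twist2 (1.14) and the receptor gene Pdgfra, which went from 138 ± 0.168 to 234 ± 2.47 CPM. Apart from the genes led by p, those of this paragraph were chosen after their values were seen. Adjusted over the list alone, 23 were lower and 8 higher. Limma's camera gave an adjusted p of 1.6e-06 with the preset correlation and an adjusted p = 0.203 with an estimated correlation.

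Osteoblast and odontoblast genes, the subject of the series title, went both ways, with more falling than rising. Of 35 tested members of 46, 21 fell, 8 rose and 6 did not pass. Sp7, encoding the transcription factor osterix that drives osteoblast differentiation, fell 17.1-fold from 23.4 ± 0.813 to 1.37 ± 0.0903 CPM (log2 fold change -3.36, SE 0.11, limma adjusted p = 2.53e-14), and Postn 16.2-fold. Spp1, encoding the bone matrix protein osteopontin, rose 2.06-fold from 372 ± 10.9 to 766 ± 31.3 CPM (limma adjusted p = 3.22e-13). Runx2, chosen after its values were seen, stood at 143 ± 2.93 CPM in shControl and 112 ± 6.34 CPM in shArl4c and also passed limma's test. The median log2 fold change was -0.34, and 22 were lower and 9 higher when adjusted over the list alone. Limma's camera called the list lower with the preset correlation (adjusted p = 0.000458), with an adjusted p = 0.508 with an estimated correlation.

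Of the 25 genes listed for ameloblasts and enamel matrix, 11 were expressed enough to be tested, and 7 of these fell, 3 rose and 1 did not pass. The listed genes Amelx, Ambn, Enam, Amtn, Odam, Mmp20 and Klk4 were not among the tested ones, so the counts do not cover them. They are named after this was seen. Slc13a5, a citrate transporter gene, fell 4.97-fold from 46.2 ± 0.809 to 9.30 ± 0.811 CPM (limma adjusted p = 3.41e-14), Adgrf4 2.59-fold from 17.5 ± 0.384 to 6.78 ± 0.867 CPM, and Nhs 2.27-fold from 29.6 ± 0.244 to 13.03 ± 0.690 CPM. The same 7 lower and 3 higher were counted adjusted over the list alone. The median was -0.49, and camera's adjusted p was 0.0115 with the preset correlation, against an adjusted p = 0.236 with an estimated correlation. Among 14 tested genes of dental epithelial progenitors and the enamel knot, 6 fell, 2 rose and 6 did not pass, and counts adjusted over the list alone were the same. Igfbp5, an insulin-like growth factor binding protein gene, fell 5.32-fold from 38.5 ± 2.01 to 7.24 ± 0.303 CPM and the homeobox gene Irx1 1.76-fold to 13.2 ± 1.65 CPM, whereas Lrig1 rose 1.76-fold (log2 fold change 0.80, SE 0.06). Limma's camera did not call this list (adjusted p = 0.264). Of 16 tested genes of dental mesenchyme and dental follicle, 10 fell, 3 rose and 3 did not pass, also when adjusted over the list alone. Prrx1, a homeobox gene of mesenchyme, fell 1.94-fold from 1132 ± 20.4 to 585 ± 16.1 CPM and Smoc2 4.04-fold to 6.50 ± 0.153 CPM, while Igfbp3 rose 3.64-fold from 8.17 ± 0.417 to 29.7 ± 2.74 CPM. Camera's adjusted p for this list was 0.0684.

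Interferon response genes rose together. All 34 tested members of the list of 35 rose, with a median log2 fold change of 1.16, and the count was 34 adjusted over the list alone. Oas3 and Oas2 rose 13.1-fold and 13.4-fold as given above, and Oasl2 3.84-fold from 15.6 ± 0.716 to 59.999 ± 1.44 CPM (log2 fold change 1.87, SE 0.06, limma adjusted p = 2.34e-14). Limma's camera called the list higher with the preset correlation (adjusted p = 1.13e-23), but with an adjusted p = 0.101 with an estimated correlation, the lowest of the 24 lists. Without shArl4c 3, 33 of 33 tested members were higher. Of the leukocyte genes, Cd68 rose from 2.79 ± 0.397 to 5.77 ± 0.207 CPM (limma adjusted p = 6.98e-05), while Ptprc, Cd74 and Lyz2 stood at 0.0505 ± 0.0437, 0.574 ± 0.233 and 1.03 ± 0.335 CPM in shArl4c and at 0.0940 ± 0.0817, 0.933 ± 0.245 and 1.24 ± 0.0228 CPM in shControl. The last 3 were chosen after their values were seen.

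Of 20 tested NF-kB and inflammatory cytokine genes, 12 rose, none fell and 8 did not pass; 14 rose when adjusted over the list alone. Birc3, encoding an inhibitor of apoptosis protein, rose 1.60-fold from 108 ± 5.94 to 173 ± 9.38 CPM (limma adjusted p = 2.57e-09), the chemokine gene Cxcl5 1.56-fold to 66.1 ± 1.53 CPM and the cyclooxygenase gene Ptgs2 1.34-fold to 90.8 ± 0.5499 CPM. The median was 0.24, with a camera adjusted p of 0.000325 at the preset correlation and an adjusted p = 0.203 with an estimated correlation. Without shControl 1, or with DESeq2, 7 members were higher.

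Cell cycle genes were higher by small amounts. Of 33 genes of G1/S and DNA replication, 26 rose, none fell and 7 did not pass, with a median log2 fold change of 0.41; 29 rose when adjusted over the list alone. Mcm5, a subunit of the replicative helicase, rose 1.53-fold from 94.5 ± 0.156 to 144 ± 11.6 CPM (limma adjusted p = 1.81e-08), Pcna, the sliding clamp, 1.46-fold from 89.8 ± 1.89 to 131 ± 5.54 CPM, and Pola1, a DNA polymerase subunit, 1.43-fold to 85.1 ± 1.80 CPM. Of 32 genes of G2/M and mitosis, 30 rose and 2 did not pass, with a median of 0.26 and the same 30 adjusted over the list alone. Ect2 rose 1.45-fold from 110 ± 4.91 to 159 ± 6.29 CPM, Anln 1.34-fold to 259 ± 5.80 CPM and the motor protein gene Kif11 1.31-fold to 98.5 ± 2.59 CPM. Limma's camera called both lists higher at the preset correlation, with adjusted p of 4.95e-10 for G1/S and 8.63e-09 for G2/M. With an estimated correlation neither list was called by camera (adjusted p = 0.236 for G1/S and adjusted p = 0.352 for G2/M).

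Genes of the list of unfolded protein and amino acid stress response mostly fell, but several of its protein folding genes did not pass. Of 30 tested members, 20 fell, 1 rose and 9 did not pass, with a median log2 fold change of -0.34; adjusted over the list alone, 20 fell and 3 rose. Chac1, which degrades glutathione, fell 2.47-fold from 60.9 ± 2.37 to 24.7 ± 1.21 CPM (limma adjusted p = 3.78e-12). Sesn2 fell 2.24-fold from 68.0 ± 5.03 to 30.3 ± 1.016 CPM and the amino acid transporter gene Slc7a5 1.86-fold from 386 ± 2.77 to 208 ± 17.0 CPM. Of genes of the unfolded protein response, Hsp90b1 (log2 fold change 0.09), Pdia4 (0.01) and Hyou1 (-0.04) did not pass. Hspa5 (-0.17) and Herpud1 (-0.65) fell. The unfolded protein response genes named here were chosen after their values were seen. Camera's adjusted p was 1.29e-06 at the preset correlation, with an adjusted p = 0.509 with an estimated correlation. Without shArl4c 3, 19 fell and 4 rose. Of 25 p53 target genes, 10 fell, 3 rose and 12 did not pass, also when adjusted over the list alone. Besides Sesn2, the falls included Zmat3 (1.29-fold lower) and the cell cycle inhibitor gene Cdkn1a, which fell 1.68-fold from 16.3 ± 1.52 to 9.73 ± 1.05 CPM. Limma's camera did not call this list (adjusted p = 0.178). Without shControl 1, shControl 2 or shArl4c 2, 1 member rose.

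Wnt and beta-catenin target genes were mostly lower. Of 18 tested, 11 fell, 2 rose and 5 did not pass, with a median log2 fold change of -0.29; adjusted over the list alone, 12 fell and 3 rose. Nkd2, a feedback inhibitor of Wnt signalling, fell 2.93-fold from 59.5 ± 3.99 to 20.3 ± 0.804 CPM (limma adjusted p = 8.45e-13) and Bambi 5.17-fold from 6.04 ± 0.225 to 1.17 ± 0.130 CPM, while the cyclin gene Ccnd1 rose 1.42-fold to 333 ± 22.2 CPM. The list was called lower by camera at the preset correlation (adjusted p = 0.00309), with an adjusted p = 0.203 with an estimated correlation. Of 27 YAP and TAZ target genes, 13 fell, 6 rose and 8 did not pass, also when adjusted over the list alone. Thbs1, encoding thrombospondin 1, fell 1.97-fold from 4040.3 ± 117 to 2046 ± 66.7 CPM and Tgfb1i1 2.29-fold to 39.9 ± 1.04 CPM, whereas Igfbp3 rose 3.64-fold. Camera's adjusted p for this list was 0.0648, and 0.0494 without shArl4c 2. Of 27 ERK feedback and immediate-early genes, 13 rose, 5 fell and 9 did not pass; adjusted over the list alone, 13 rose and 6 fell. Ereg, a growth factor gene, rose 1.97-fold to 46.0 ± 1.68 CPM and the transcription factor gene Egr1 1.48-fold to 67.1 ± 0.651 CPM, while the ERK inhibitor gene Spry1 fell 3.85-fold from 7.37 ± 0.166 to 1.92 ± 0.0432 CPM. Camera called this list higher (median 0.18, adjusted p = 0.0400) at the preset correlation, and the adjusted p was 0.599 with an estimated correlation. The call ended without shControl 1 (camera adjusted p = 0.0655), without shArl4c 2 (0.0914) and under 4 of the other settings; 3 members fell without shControl 1 or shControl 3.

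Basement membrane and hemidesmosome genes went both ways. Of 26 tested, 12 fell, 7 rose and 7 did not pass, also when adjusted over the list alone. Besides Tnc, Npnt, encoding nephronectin, fell 4.46-fold from 223 ± 4.91 to 50.05 ± 1.68 CPM, whereas the laminin gene Lama1 rose 2.57-fold from 25.4 ± 0.969 to 65.4 ± 1.95 CPM (limma adjusted p = 9.28e-13). Limma's camera did not call the list (adjusted p = 0.229), but it was called lower from the statistics of edgeR (0.00153) and DESeq2 (0.00245) on the recovered reads. Of 38 epithelial junction genes, 11 were tested: 4 fell, 3 rose and 4 did not pass, against 5 and 4 adjusted over the list alone. Cdh3, encoding P-cadherin, fell 3.55-fold from 61.1 ± 2.498 to 17.2 ± 1.61 CPM and Perp 1.89-fold to 13.3 ± 0.768 CPM. The median of this list was 0.01 and its mean -0.15, so that they differed in sign, and camera did not call it (adjusted p = 0.735). Of 43 genes of stratified epithelium, 7 were tested: 4 rose, 1 fell and 2 did not pass, also when adjusted over the list alone. Krt80 rose 2.02-fold to 24.5 ± 0.448 CPM and S100a7a 2.10-fold to 14.3 ± 1.63 CPM, while Notch3 fell 1.18-fold to 25.1 ± 0.456 CPM (camera adjusted p = 0.229). Without shControl 1 or shArl4c 2, or with DESeq2, 2 members rose. With no filter on low values, 22 members were tested, 7 rose and 1 fell, and camera called the list higher (adjusted p = 0.0187).

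Markers of leukocytes, endothelium and nerve were mostly below the filter, with 8 of 25 tested. Of these, Cd68 rose 2.07-fold to 5.77 ± 0.207 CPM, Ncam1 fell 1.41-fold to 107 ± 1.21 CPM and Tubb3 1.86-fold to 4.75 ± 0.101 CPM, and 5 did not pass, also when adjusted over the list alone. The median was 0.01 and the mean -0.01, and camera did not call the list (adjusted p = 0.858). With the stricter filter 2 members were tested, both lower, and camera called the list lower (adjusted p = 0.0218). Of 23 cholesterol synthesis genes, 5 fell, 2 rose and 16 did not pass, also when adjusted over the list alone. Insig1, a sterol-sensing regulator, fell 2.02-fold from 143 ± 7.11 to 70.7 ± 4.88 CPM and Cyp51 1.18-fold to 214 ± 11.9 CPM, and Stard4 rose 1.16-fold to 66.5 ± 2.08 CPM. The median of this list was 0.02 against a mean of -0.04, and camera gave an adjusted p of 0.735. Of 30 hypoxia and glycolysis genes, 13 rose, 4 fell and 13 did not pass, also when adjusted over the list alone, among them the glycolytic genes Gpi1 (1.35-fold higher), Pgk1 (1.23-fold) and Hk1 (1.21-fold). Camera's adjusted p was 0.145, and 0.0318 without shArl4c 3. Without shArl4c 3, 7 cholesterol synthesis genes were higher and 5 lower, and without any 1 of the shControl libraries 3 were lower.

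Of the 13 mitochondrially encoded genes, 4 fell and 9 did not pass, also when adjusted over the list alone. mt-Cytb fell 1.19-fold from 879 ± 14.3 to 740 ± 15.9 CPM (limma adjusted p = 3.53e-05), mt-Nd1 1.38-fold to 364 ± 11.1 CPM and mt-Nd4 1.23-fold to 619 ± 34.2 CPM. The median was -0.30, and camera called the list lower at the preset correlation (adjusted p = 0.0400), with an adjusted p = 0.599 with an estimated correlation. The call ended without shControl 1 (camera adjusted p = 0.101), without shArl4c 3 (0.112), when 2 members were lower, and without shArl4c 4 (0.0578); 8 members were lower without shControl 3. It also ended with quantile normalization (0.108), when 3 members were lower and 1 higher, and with edgeR (0.222), DESeq2 (0.0669, 7 lower) and the correction for GC content and length (0.0866). Of 48 cytosolic ribosomal protein genes, 42 did not pass, 4 fell and 2 rose, and adjusted over the list alone 2 fell and 1 rose. Rpl22 fell 1.38-fold from 142 ± 6.89 to 103 ± 8.15 CPM and Rps20 1.245-fold to 273 ± 24.8 CPM, while Rpl14 rose 1.16-fold to 364 ± 26.9 CPM. Camera did not call this list (median 0.02, adjusted p = 0.819), but without shArl4c 3, 24 members were higher and 4 lower and camera's adjusted p was 0.00917. Without shControl 1, 2 members were lower.

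Across the 24 lists, limma's camera called 12 at the preset correlation, 5 higher and 7 lower, and 0 with an estimated correlation. The correlations were estimated from only 6 libraries. Even the interferon list, with all 34 members higher, was then not called (camera adjusted p = 0.101). A missing call at an estimated correlation is therefore weak evidence against a list. Splits of the libraries into groups that mix shControl and shArl4c also gave 5 to 10 called lists at the preset correlation, and 0 changed genes. Such splits hold most of the difference between shControl and shArl4c as spread within groups, which hides changed genes. Part of that difference stays between the mixed groups, so their called lists give no background rate. Limma's fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, gave an adjusted p under 0.05 for 18 lists, and for 23 when changes in either direction were counted. The lists share members, 8 in the case of the fibroblast list, 6 for the osteoblast list and 4 for the SRF list.

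**Figure D3:**
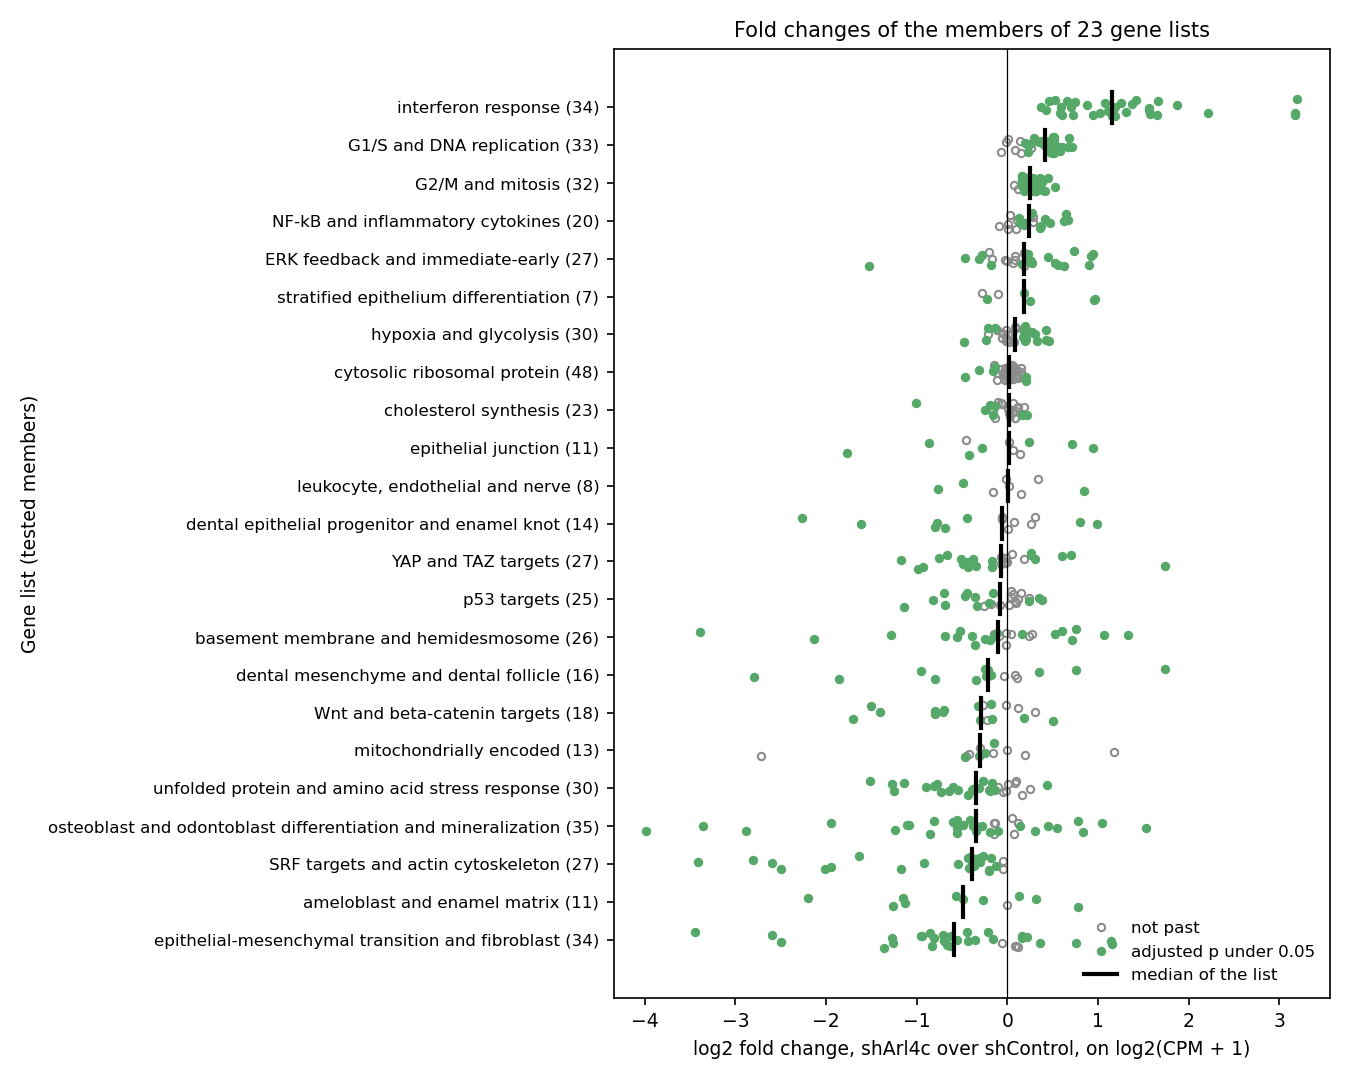
Log2 fold changes of shArl4c over shControl (on CPM + 1) of the tested members of 23 of the 24 gene lists, ordered by median, with the number tested in brackets; filled points passed the limma adjusted p of 0.05, open points did not, and black bars mark medians. The interferon list lies furthest to the right, with a median of 1.16 and all 34 members filled, and the fibroblast list furthest to the left, with a median of -0.59.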

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

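Plain CPM, the correction for GC content and length, and the counts without shArl4c 3 were chosen after the result was seen; the other settings were planned. The Arl4c level, lower in shArl4c, kept its direction and passed the test under all settings, with log2 fold changes of -1.09 (pseudocount 5) to -1.57 (edgeR). The number of changed genes stayed within 1.5 times 5445 in all settings, from 4108 (DESeq2) to 6885 (array weights), with 4347 to 6625 when 1 library was left out. At least 2-fold changes numbered 558, but 235 with a pseudocount of 5, which shrinks the changes of low genes, and 342 with the stricter filter, which tests 11281 genes. Plain CPM gave 59.4% of calls higher against 51.2%. The camera test of cholesterol synthesis turned its direction, never past the threshold, with array weights (adjusted p = 0.923) and without shArl4c 3 (0.640, with 0.386 to 0.7998 over the left-out runs). That of ribosomal proteins turned with the GC and length correction (0.774) and without shControl 3 (0.974), shArl4c 2 (0.386) or shArl4c 4 (0.740), and passed as higher without shArl4c 3 (0.00917); the cause was not tested. The calls of the ERK and mitochondrial lists ended in several settings, while calls appeared in some for YAP and TAZ targets (0.0116 with DESeq2), basement membrane (0.00153 with edgeR), stratified epithelium (0.0187 with no filter), leukocyte, endothelial and nerve markers (0.0218 with the stricter filter, on 2 genes) and hypoxia (0.0318 without shArl4c 3). Over the list tests, 402 results kept side and direction, 13 lost the call, 11 gained it and 6 turned. Over named genes 1563 results were the same and 11 lost the call, in Stard4, Notch3, mt-Nd1, mt-Nd4 and Rpl14. The named genes were chosen for large changes or small p in these data, so their stability does not describe changed genes in general. Of the 5445 changed genes, 4080 were also called with DESeq2, 4277 by limma without trend and robust moderation and 4289 without shControl 2. All of these kept their direction. No paired analysis was possible because the columns, numbered 1 to 3 and 2 to 4, cannot be tied to the replicate numbers of the sample titles. The design set no block by replicate number. At 12316770 to 14976113 reads per library, 7292 genes lay below the filter.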

Other observations

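The tests of leukocyte RNA, GC content and length, the hairpin, the splitting of histone reads, S phase, the mesenchymal share and scaling were chosen after the result was seen, as were the symbol families and the genes named here; that of RNA without a poly(A) tail was chosen after the rise of histone genes was seen but before its own values were, and that of other splits before its values were seen.

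Histone genes rose as a group. Genes were sorted into 223 families of 8 to 150 tested members by the leading letters of their symbols, and limma's camera called 7 at the preset correlation, 6 higher and 1 lower, none with an estimated correlation (adjusted p = 0.957 for each). Of 60 histone genes (symbols starting with Hist), 41 rose and none fell, with a median log2 fold change of 0.57. Their summed level went from 3653 ± 167 to 5395 ± 799 CPM (SD, n = 3), 1.48-fold higher. Among 29 collagen genes (Col), 19 fell and 2 rose, with a median of -0.52; Col2a1, a cartilage collagen gene, went from 25.6 ± 1.09 to 1.87 ± 0.499 CPM (log2 fold change -3.22, limma adjusted p = 1.84e-13). The families Ifi (11 of 11 higher), Mcm (9 of 10), Nup (12 of 19), Ddx (12 of 35) and Il (12 higher and 4 lower of 27) were also called higher. Some families share genes with the fixed lists, such as Mcm5 with the G1/S list, Ifi44 with the interferon list and Col6a3 with the fibroblast list. They are therefore not separate evidence from those lists. All 7 kept their sign of median under each scaling, histones from 0.57 to 0.60 and collagens from -0.53 to -0.42.

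Some further genes, outside the fixed interferon list and not tested as a group, also differed. H2-K1 went from 31.2 ± 1.24 to 61.3 ± 4.82 CPM and H2-D1 from 38.3 ± 0.695 to 88.4 ± 5.12 CPM, Tap1 from 10.97 ± 1.08 to 23.7 ± 2.11 CPM, Psmb8 from 2.80 ± 0.724 to 11.3 ± 1.19 CPM and Psmb9 from 1.16 ± 0.366 to 2.89 ± 0.117 CPM, all past limma's test. B2m, which encodes the light chain of the class I molecules whose heavy chains H2-K1 and H2-D1 encode, stood at 131 ± 3.25 and 133 ± 4.55 CPM (limma adjusted p = 0.711). H2-K1 and H2-D1 are close in sequence, so their split of reads is uncertain.

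The rise of the interferon list may come from less Arl4c, from the hairpin or its vector, or from another difference between the groups' cultures. The labels do not say whether the samples of a group were separate cultures, so such a difference cannot be told apart. Leukocyte RNA would bring all abundant leukocyte transcripts, but the 7 leukocyte genes of the fixed list found in the table summed to 7.58 ± 0.622 CPM in shControl and 9.96 ± 0.764 CPM in shArl4c, a rise of 0.396% of that of the summed interferon list (630.2 ± 14.2 to 1231 ± 30.6 CPM); Cd68 rose, and the sum of the other 6 went from 4.79 ± 0.355 to 4.19 ± 0.620 CPM. Bias from GC content or transcript length is argued against by a list median of 1.15 after correction (1.16 before). An innate response to the hairpin or its vector cannot be told apart from an effect of Arl4c, since the labels tell apart 1 Arl4c hairpin group. A second hairpin or a rescue would separate them. The shControl cells carried a hairpin too, a control one. These limits hold for every other difference between shControl and shArl4c given here, since each rests on the same groups.

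The rise of histone genes is consistent with a larger share of cells in S phase, a hypothesis for which the median of the G1/S list, 0.41, has the sign it needs. More RNA without a poly(A) tail in the shArl4c libraries is argued against only weakly, by 6 other such RNAs. Their median log2 fold change was -0.15 (SE over genes 0.13), against 0.57 (SE over genes 0.04) for histones. None of the 6 passed limma's test, and some lay at low levels, such as Snora73a at 2.14 CPM in shControl. Reads split differently among near-identical histone genes would leave their sum equal, but the lowest shArl4c sum was 1.18 times the highest shControl sum. That lowest sum, 4485 CPM, was in shArl4c 3, against 5983 and 5717 CPM in shArl4c 2 and 4. Cell cycle phase itself was not measured.

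The fall of the list of SRF targets and actin cytoskeleton may reflect lower expression within mDE6 cells. A smaller share of mesenchymal cells in the cultures, acting alone, would lower mesenchymal markers together. Of 34 tested members of the fibroblast list, 23 fell and 7 rose, among them Pdgfra and Pdgfrb (log2 fold changes 0.76 and 0.16). Over all tested genes 2790 of 14740 rose, so a few rises in a list cannot exclude a smaller share combined with other changes. Scaling by a few abundant genes is argued against by 24 of 27 SRF and actin members still lower under the scaling that left the fewest. A shift between kinds of mesenchymal cell stays open.

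The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split, 1 of 10 in each case, gave 5445 changed genes, 2790 higher, 2655 lower and 558 at least 2-fold, and the highest of the other splits by limma was 0 for each. By camera at the preset correlation the real split called 12 lists and the other splits 5 to 10. Each of the other splits mixes shControl and shArl4c in both groups. Most of the difference between shControl and shArl4c then counts as spread within groups, so 0 changed genes was to be expected. Part of it stays between the mixed groups, so their called lists give no background rate.

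Library levels of mt-Co3 ran from 0 to 211 CPM and of mt-Co2 from 0 to 12.99 CPM over the 6 libraries, and those of mt-Nd4l from 2.32 to 17.1 CPM; none of the 3 passed limma's test (adjusted p = 0.426, 0.544 and 0.887).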
